A study of Mus musculus with 8 samples.

How the data were processed

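Gene expression was measured on 8 microarrays of total RNA from primary mouse articular chondrocytes, the cells of joint cartilage, taken from the knee surfaces of 5-day-old wild-type ICR mice. Cells had been infected with a control adenovirus (Ad-null, 4 arrays) or with an adenovirus carrying the zinc transporter ZIP8 (Ad-Zip8, 4 arrays), and RNA was collected 24 h after infection. Per the labels, the arrays are biological replicates. No label says whether the cultures came from separate animals or pools, so the p-values measure the spread between these samples.

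The authors deposited 1 value per probe set and array on the log2 scale. These log2 values were made with RMA, per the submitters' processing notes. RMA corrects background, forces the arrays to a common distribution and summarises the probes of each probe set. The version of RMA, the probe set annotation and any filter are not given in the sources used here. Per the labels' protocols, RNA was labelled with biotin through a whole-transcript labelling kit. The values ran from 0.85 to 13.8 over all arrays, and array medians lay between 5.04 and 5.11. Differences at the upper end of this range are compressed as features approach saturation, and differences at the lower end are compressed by background. Scanner files and detection calls were not used here, so no gene was called absent. The number of arrays limits the precision.

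Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and were not named, and 16010 were not listed in that annotation and stay unnamed here. Symbols were checked through Entrez identifiers against a mouse reference gene table (assembly GRCm38.p6). That table held 23328 of the 23521 identifiers, and no symbol changed. For the 1082 genes with several probe sets the one with the highest mean over the 8 arrays was kept, which left 22180 genes. No gene had probe sets called in opposite directions. The array's genome build is not given in the sources used here, so no coordinates are printed. Some genes of interest, such as the zinc exporter gene Slc30a1, were not analysed here. All columns of values belonged to the 8 samples.

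Ad-Zip8 was compared with Ad-null by a linear model with empirical Bayes variance moderation (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), without covariates and without a filter on dim genes. Values were adjusted by the Benjamini-Hochberg method over the 22180 genes, with a threshold of 0.05. All adjusted p-values of single genes come from this limma fit unless stated. Fold changes are differences of mean log2 values, Ad-Zip8 minus Ad-null, with the moderated standard error (SE). A count at 2-fold or more requires a log2 change of at least 1 in either direction.

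A set of 29 gene lists was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera asks whether a list's genes shift more than the other genes. The lists covered the zinc response, zinc transporters, iron and manganese handling, heat shock, oxidative stress genes driven by NRF2, endoplasmic reticulum (ER) stress, matrix-degrading enzymes and their inhibitors, inflammatory mediators, interferon response, cartilage matrix, chondrogenic regulators, hypertrophy, fibroblast genes, glycosaminoglycan synthesis, hypoxia targets, cholesterol and oxysterol genes, p53 targets, cell cycle, TGF-beta and BMP response, Wnt signalling, immediate early genes and ribosomal proteins. Marker lists of macrophages, endothelium, skeletal muscle, osteoclasts, adipocytes and blood cells were included. Camera with an estimated correlation passed 0 of the 29 lists (10 had an unadjusted p under 0.05), against 15 at the preset value. Limma's fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, passed 22 lists, including all 15. Counts of list members are given over all genes tested and, where named so, adjusted over the list alone.

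The samples, tests, gene lists, naming rule and alternatives were fixed before the data were examined. The rule named Slc39a8, the 12 genes with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap, 10 further preset genes (an 11th, Slc30a1, was not analysed here) and up to 4 list members with the smallest adjusted p. Predicted genes, small RNAs and receptor or immunoglobulin segments were left out of the top genes.

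Both groups carry replicate numbers 1 to 4, with no statement that a number marks a shared culture. Deviations from the group means correlated between same-numbered arrays at 0.11 to 0.37, and between other arrays at -0.27 to 0.16, and 7 of 8 arrays correlated best with their own number. Because each same-numbered correlation exceeded 0.1, the numbers were taken to pair the samples in an alternative fit with a replicate block. That pairing was inferred from the data and is uncertain. Ad-null replicate 2 correlated at 0.16 with Ad-Zip8 replicate 1, above the 0.11 of the pair numbered 1. The main fit left the numbers out. The blocked fit is given where it changed the call of a named gene or of a list, or moved a list's count of genes by over 1.5 times.

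The fit was tested on simulated data with the real means and moderated residual SDs of the 22180 genes and 200 changed genes, in 10 runs. It recovered 63.1% of genes changed by 0.5 on the log2 scale, 97.8% of those changed by 1 and 99.7% of those changed by 2, and 4.42% of its calls were false. A further small list of genes shifted by 0.5 was counted among the calls and not as false. The simulated noise was independent between genes and arrays, and the data called 2352 genes, so these shares may not hold for the real calls. Alternatives were centring each array on its median, repeating quantile normalization, leaving out dim genes, a variance trend with a robust prior, array weights, the replicate block, averaging a gene's probe sets, testing all probe sets, and leaving out each array in turn.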

Results

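The data comprised 8 arrays in 2 groups of 4, chondrocytes 24 h after infection with Ad-null or Ad-Zip8. Zip8 is the protein name of the Slc39a8 product, a transporter that carries zinc and other divalent metals into cells. The comparison addresses how raised ZIP8 changes gene expression in chondrocytes. Over the 22180 genes, arrays correlated at 0.991 to 0.994 within a group and at 0.979 to 0.986 between groups, so no array duplicated another.

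Slc39a8 itself was 30.4-fold higher in the Ad-Zip8 cells. Its mean was 6.20 ± 0.07 (SD, n = 4) on the log2 scale with Ad-null and 11.1 ± 0.15 (SD, n = 4) with Ad-Zip8, a log2 difference of 4.93 with an SE of 0.09 (limma adjusted p = 3.49e-09), and the groups did not overlap. Of the 22180 genes, 1216 rose and 1136 fell at an adjusted p under 0.05, which is 10.6% of those tested. The increases were larger: 248 genes rose at least 2-fold and 79 fell at least 2-fold. The count of genes that fell was the less stable one, at 721 without Ad-null replicate 1 and 708 without Ad-Zip8 replicate 1. Differences are compressed at both ends of the scale, so the sizes of change given below are uncertain for genes with a group mean below the array medians (Cxcl3, Saa2, Il17b, Car3, Aspn, Mmp12, Il6, Isg15, Chst3, Hspa1a, Ch25h, Birc5 and Fabp4) or above 13 (Saa3, Col2a1, Acan and Fth1).

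**Figure D1:**
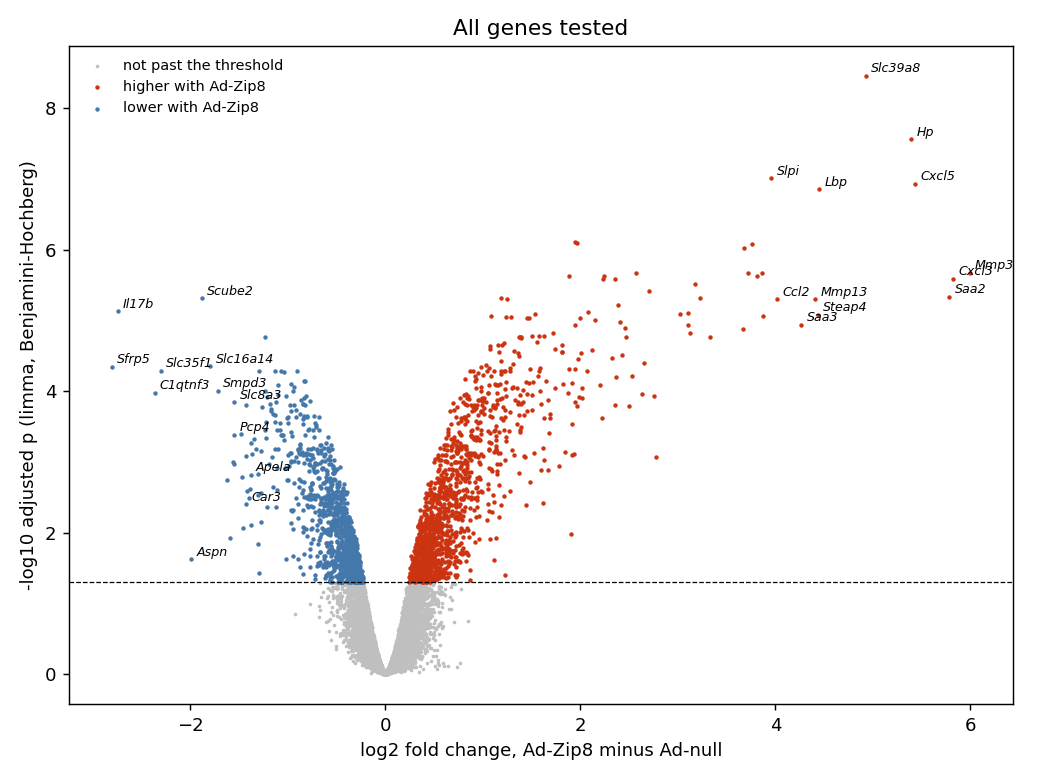
The horizontal axis is the log2 fold change of Ad-Zip8 over Ad-null for each of 22180 genes, and the vertical axis is -log10 of the limma adjusted p. Red points are the 1216 genes that rose, blue points the 1136 that fell, the dashed line marks an adjusted p of 0.05, and the 12 largest changes of each direction that the naming rule allows carry their symbols.

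Beside Slc39a8, the 12 largest increases that the naming rule allows held Mmp3, which encodes stromelysin 1 (63.7-fold, log2 change 5.99, SE 0.27, adjusted p = 2.1e-06), the chemokine genes Cxcl3 (56.7-fold, SE 0.28 on the log2 scale) and Cxcl5 (43.1-fold, SE 0.16), and the acute-phase genes Saa2 (55.1-fold, SE 0.30) and Hp, which encodes haptoglobin (42.1-fold, SE 0.13). Lbp, the gene of the lipopolysaccharide-binding protein, rose 21.8-fold, the metalloreductase gene Steap4 21.6-fold and the collagenase 3 gene Mmp13 21.3-fold. Saa3 rose 19.2-fold, the monocyte chemoattractant gene Ccl2 16.2-fold and the protease inhibitor gene Slpi 15.6-fold. All 12 had an adjusted p of 1.16e-05 or lower. Saa2 has a near-identical neighbour in Saa1, so its value is uncertain between them. Cxcl3 and Saa2 had Ad-null means of 2.76 and 3.49 on the log2 scale, far below the array medians, and Saa3 had an Ad-Zip8 mean of 13.5, near the top of the scale, so the sizes and ranks of these 3 changes are uncertain.

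The 12 largest decreases were smaller than the 12 largest increases. Sfrp5, which encodes a secreted Wnt antagonist, was 6.98-fold lower (log2 change -2.80, SE 0.22, adjusted p = 4.48e-05), and the cytokine gene Il17b was 6.70-fold lower (-2.74, SE 0.16), with a low Ad-Zip8 mean of 4.38 that leaves the size and rank of its change uncertain. C1qtnf3 was 5.16-fold lower, Slc35f1 4.94-fold and Scube2 3.69-fold. The monocarboxylate transporter family gene Slc16a14 was 3.47-fold lower, the neutral sphingomyelinase gene Smpd3 3.29-fold and the sodium-calcium exchanger gene Slc8a3 2.93-fold. Pcp4 was 2.92-fold lower, the carbonic anhydrase gene Car3 2.70-fold and Apela 2.61-fold. Aspn, which encodes the matrix protein asporin, was 3.97-fold lower and had the largest SD of the named genes (0.89 with Ad-null, n = 4). Its lowest value in each group was in replicate 3, and with the replicate block its adjusted p was 6.89e-04. Without the block its adjusted p of 0.0236 rose to as much as 0.0689 without Ad-null replicate 1, 2 or 4 or Ad-Zip8 replicate 1, and was 0.0777 with the variance trend.

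Among matrix-degrading enzymes, 12 of 36 measured genes rose, 5 fell and 19 did not pass the test. Beside Mmp3 and Mmp13, Mmp9 rose by 2.20 on the log2 scale (SE 0.19, adjusted p = 8.05e-05) and Mmp12 3.94-fold (1.98, SE 0.15, adjusted p = 3.53e-05). Adamts5, which encodes an aggrecan-cleaving enzyme, went from 5.90 ± 0.33 to 7.42 ± 0.33 (SD, n = 4 each), a 2.87-fold rise (adjusted p = 7.44e-04). The list's shift passed camera (adjusted p = 0.00113; adjusted p = 0.111 with an estimated correlation), and adjusted over the list alone 13 genes rose and 5 fell. Of 8 inhibitors, Serpina3n rose 4.71-fold (SE 0.11 on the log2 scale) and Timp1 1.74-fold (SE 0.12), while Timp3 fell 1.34-fold (SE 0.06), and 5 did not pass. Adjusted over the list alone these counts were equal, at 2 and 1. Serpina3n, a serpin gene also counted among the acute-phase genes below, had the largest change of the list. Timp2 (log2 change 0.02), Timp4 (0.05) and Reck (-0.09) were among those that did not pass. The inhibitor list had a median log2 change of -0.01 and a mean of 0.30. Its camera test (adjusted p = 0.358) pointed upward, and limma's fry passed it as higher (adjusted p = 0.00293).

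Inflammatory mediators rose broadly: 25 of 38 measured genes rose, 1 fell and 12 did not pass, with a median log2 change of 0.86. Ccl5 rose 13.6-fold (log2 change 3.76, SE 0.15, adjusted p = 8.33e-07), Cxcl1 by 3.81 on the log2 scale (SE 0.18, adjusted p = 2.32e-06) and Nfkbiz, a regulator of NF-kB target genes, 5.12-fold (2.36, SE 0.11). Il6 rose 3.78-fold from a low Ad-null mean of 3.91 (SE 0.25 on the log2 scale, adjusted p = 8.00e-04) and Ptgs2, the gene of cyclooxygenase 2, rose 2.25-fold (SE 0.16, adjusted p = 0.00105). The growth factor gene Csf1 was the 1 member that fell (1.32-fold, adjusted p = 0.00279) and is named for that reason, after its value was seen. The inflammatory list passed camera (adjusted p = 1.11e-19; adjusted p = 0.0520 with an estimated correlation), and adjusted over the list alone 26 rose and 1 fell. Macrophage markers, which would report another source of such genes, had a median log2 change of -0.04: of 15, Cd14 (2.63-fold) and Cd68 (1.78-fold) rose, Laptm5 fell (1.65-fold) and 12 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.926. Interferon response genes moved little: 5 of 26 rose, among them Irf1 (1.38-fold), Stat2 (1.58-fold) and Isg15 (1.55-fold), and 21 did not pass. The interferon list passed camera (adjusted p = 6.56e-05; adjusted p = 0.111 with an estimated correlation), also with 5 genes adjusted over the list alone, and 3 rose without Ad-Zip8 replicate 1.

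**Figure D2:**
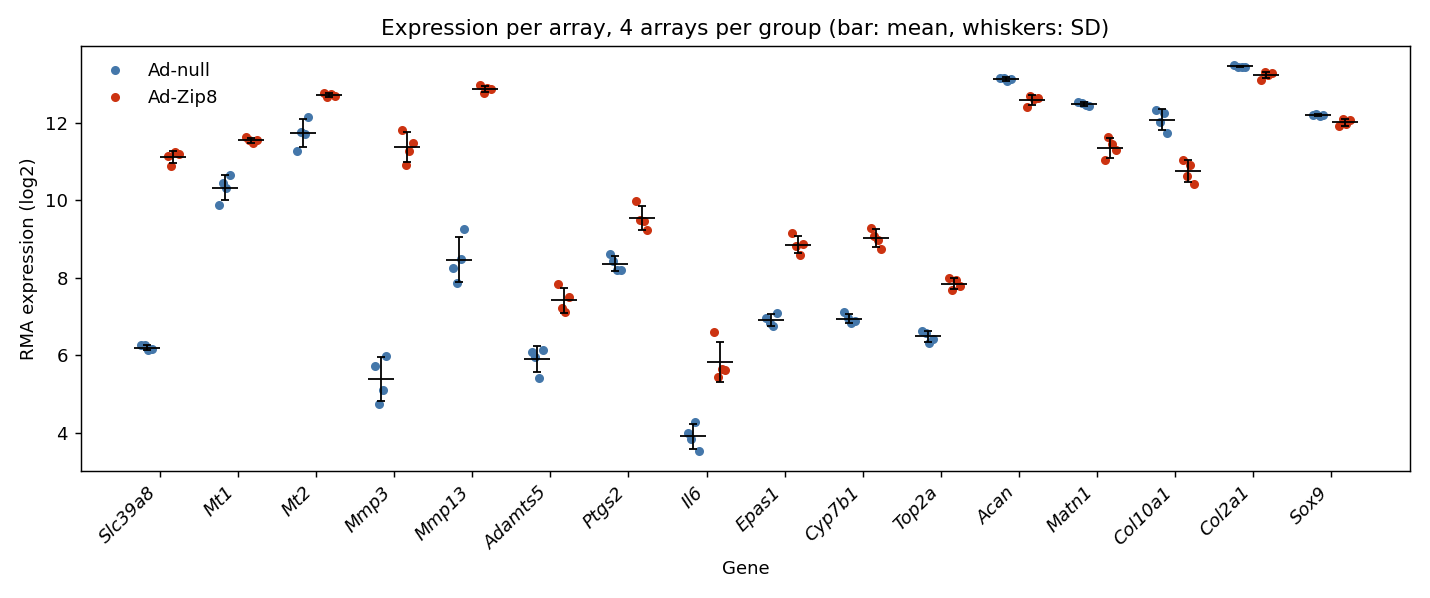
Each point is the log2 RMA expression of 1 gene on 1 array, blue for Ad-null and red for Ad-Zip8, with the mean and SD over 4 arrays. Slc39a8, Mmp3 and Mmp13 stand far apart between groups, while Col2a1 and Sox9 differ by 0.22 and 0.19 log2 units near the top of the scale.

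Cartilage matrix genes were lower: 16 of 28 measured genes fell, 1 rose and 11 did not pass, with a median log2 change of -0.35. Matn1, which encodes matrilin 1, fell 2.20-fold (log2 change -1.14, SE 0.12, adjusted p = 2.16e-04). Col9a3, a chain of collagen IX, fell 1.55-fold (SE 0.08 on the log2 scale), Ogn 1.51-fold (SE 0.07) and Acan, the gene of the main cartilage proteoglycan, 1.46-fold (-0.54, SE 0.08, adjusted p = 0.00181). Col2a1, the gene of the main cartilage collagen, had a log2 change of -0.22 (SE 0.07, adjusted p = 0.0790), with both groups above 13 on the log2 scale, and it passed after dim genes were left out (adjusted p = 0.0206) and with the variance trend (adjusted p = 0.00244). The 1 gene that rose was Prg4, which encodes lubricin (3.58-fold, 1.84, SE 0.23, adjusted p = 7.19e-04). The cartilage matrix list passed camera (adjusted p = 2.41e-08; adjusted p = 0.128 with an estimated correlation), and adjusted over the list alone 18 fell and 1 rose.

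Chondrogenic regulators were lower in 5 of 19 cases, with none higher and 14 not past the test. Fgfr3 fell 2.11-fold (log2 change -1.08, SE 0.12), Bmp7 1.93-fold (-0.95, SE 0.08) and Tgfb2 1.66-fold (-0.73, SE 0.10). Sox9, the transcription factor gene that drives chondrocyte identity, had a log2 change of -0.19 (SE 0.07, adjusted p = 0.137) and passed with the variance trend (adjusted p = 0.0125) and after dim genes were left out (adjusted p = 0.0431). This list passed camera (adjusted p = 0.00266; adjusted p = 0.188 with an estimated correlation). Adjusted over the list alone 10 fell and 3 rose, and under either rescaling of the arrays 3 fell. With the replicate block 7 fell and 2 rose, and 1 rose with repeated quantile normalization and without Ad-null replicate 1 or Ad-Zip8 replicate 3. Leaving out each array in turn gave 3 to 5 lower genes, with 3 in each case except without Ad-null replicate 3 (4) and Ad-Zip8 replicate 2 (5). Glycosaminoglycan synthesis genes fell in 7 of 23 cases and rose in 2, with Chst3 (1.57-fold), Xylt1 (1.48-fold) and Csgalnact1 (1.38-fold) lower. That list passed camera (adjusted p = 5.77e-04; adjusted p = 0.178 with an estimated correlation), and adjusted over the list alone 10 fell and 3 rose.

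Hypertrophy genes, which mark chondrocytes on the way to mineralisation, went both ways, with 7 of 16 lower, 3 higher and 6 not past the test. Col10a1 fell 2.51-fold (log2 change -1.33, SE 0.16, adjusted p = 6.57e-04), the parathyroid hormone receptor gene Pth1r 2.01-fold and Mef2c 1.72-fold, whereas Pdpn rose 1.84-fold. Camera did not pass this list (adjusted p = 0.172, but 0.0360 without Ad-null replicate 4), whereas limma's fry passed it as lower (adjusted p = 0.0461). The counts adjusted over the list alone were also 7 and 3. Fibroblast genes were likewise split, with 5 of 19 higher and 6 lower. Lum (1.90-fold) and Dcn (1.63-fold) rose, and Tnc (2.23-fold) and Acta2 (1.64-fold) fell. The fibroblast list's median log2 change was -0.06 and its mean 0.02, camera pointed downward (adjusted p = 0.579), and adjusted over the list alone 5 rose and 8 fell.

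**Figure D3:**
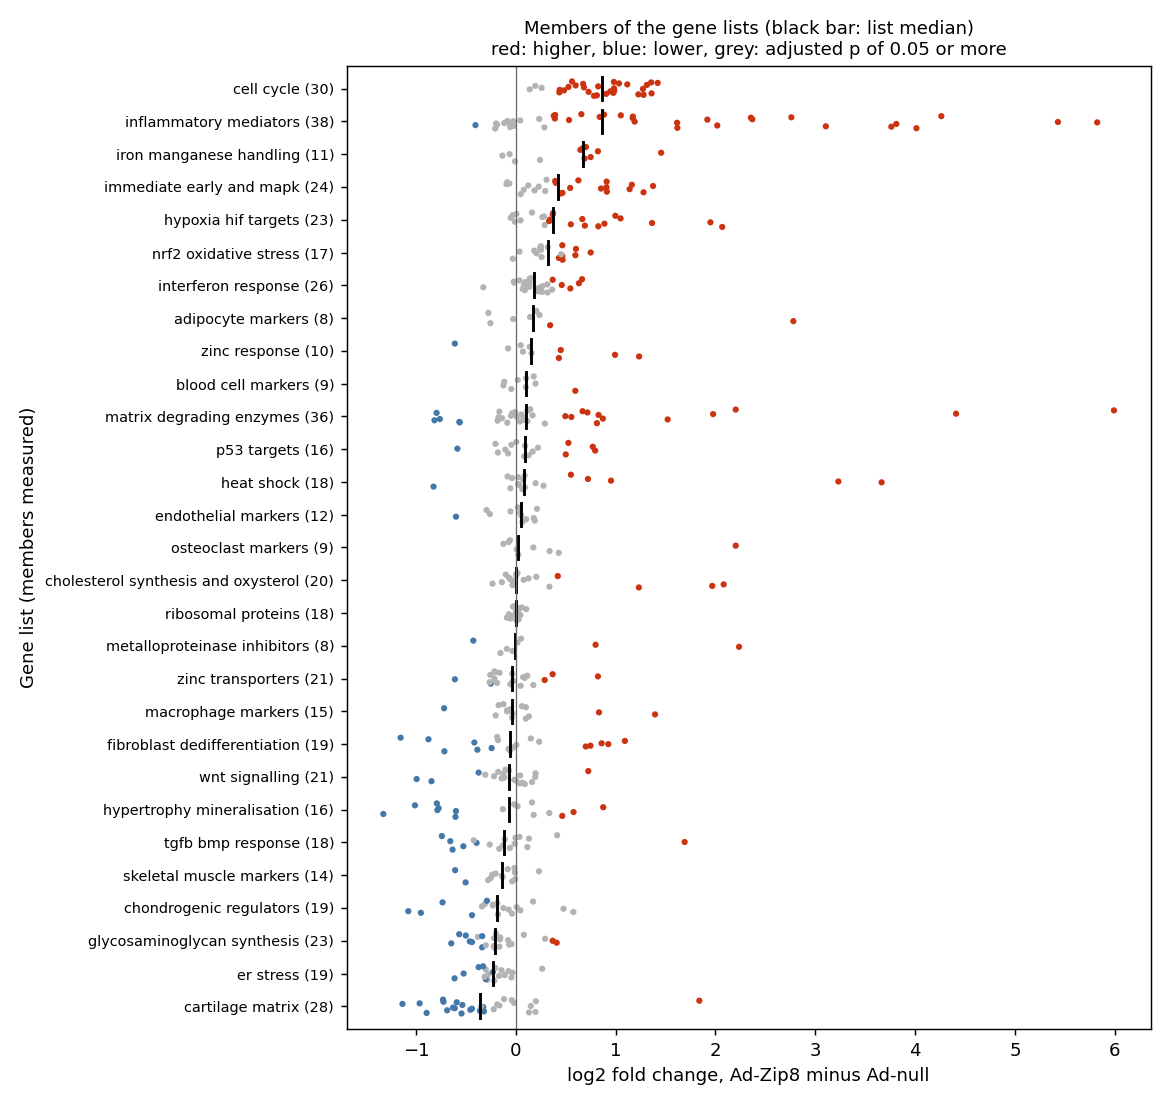
Each row is 1 of the 29 gene lists with its number of measured members, each point the log2 fold change of 1 member (red rose, blue fell, grey not past an adjusted p of 0.05), and each black bar the list's median. Cell cycle and inflammatory lists have the highest medians, 0.87 and 0.86, and cartilage matrix the lowest, -0.35.

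Of 10 measured zinc response genes 4 rose, 1 fell and 5 did not pass, with equal counts adjusted over the list alone. Those that rose were Mt1, Mt2, Ndrg1 (1.37-fold) and Gclc (1.35-fold), the last also counted in the NRF2 list. The test took the list as 1 set, so a member that zinc lowers would count against its rise. The metallothionein genes Mt1 and Mt2, which encode zinc-binding proteins, rose 2.35-fold (log2 change 1.24, SE 0.14, adjusted p = 4.45e-04) and 1.99-fold (0.99, SE 0.16, adjusted p = 0.00262), Mt2 reaching 12.7 on a scale that ended at 13.8. The list passed camera (adjusted p = 0.00612; adjusted p = 0.128 with an estimated correlation). The member that fell, the zinc importer gene Slc39a10 (1.53-fold, adjusted p = 0.0407), did not pass with the replicate block (adjusted p = 0.0699) or with arrays centred on their medians (adjusted p = 0.0561), and of the 8 fits with 1 array left out it passed in those without Ad-null replicate 3 or Ad-Zip8 replicate 3 (adjusted p up to 0.0989 in the others). Apart from Slc39a8, 3 of 21 zinc transporter genes rose and 2 fell, with Slc39a14 the largest change (1.77-fold, SE 0.07 on the log2 scale, adjusted p = 1.09e-04). Camera did not pass the transporters (adjusted p = 0.545). Adjusted over the list alone 3 rose and 5 fell, and with the replicate block 2 rose and 0 fell. With arrays centred on their medians 0 fell, and with repeated quantile normalization 1 fell. Leaving out each array in turn gave 1 higher, except without Ad-null replicate 2 (3) and Ad-Zip8 replicate 2 (2), and 0 lower, except without Ad-null replicate 3 or 4 or Ad-Zip8 replicate 3 (1).

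Iron and manganese genes rose in 7 of 11 cases with none lower. Slc11a2, a divalent metal importer gene, rose 2.74-fold (log2 change 1.46, SE 0.09, adjusted p = 9.32e-06), the ferritin heavy chain gene Fth1 1.61-fold (SE 0.07) and the transferrin receptor gene Tfrc 1.63-fold (SE 0.11). The list passed camera (adjusted p = 3.93e-07; adjusted p = 0.101 with an estimated correlation), and 8 rose adjusted over the list alone. Oxidative stress genes of the NRF2 list rose in 7 of 17 cases with none lower, among them Slc7a11 (1.52-fold), Txnrd1 (1.38-fold) and Hmox1 (1.68-fold). That list passed camera (adjusted p = 1.95e-08; adjusted p = 0.111 with an estimated correlation), 13 rose adjusted over the list alone, and 10 rose when arrays were quantile normalized again.

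Heat shock genes were dominated by the inducible chaperone genes Hspa1a and Hspa1b, which rose 12.7-fold (log2 change 3.66, SE 0.23, adjusted p = 1.32e-05) and 9.39-fold (3.23, SE 0.17, adjusted p = 4.84e-06). The 2 genes are near-identical, so each value is uncertain. Of 18 members 5 rose, Hspa4l among them (1.94-fold), the small chaperone gene Cryab fell (1.77-fold), and 12 did not pass, so the median log2 change was 0.08 against a mean of 0.50. The list passed camera (adjusted p = 0.00111; adjusted p = 0.188 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone. ER stress genes did not rise: 6 of 19 fell and 13 did not pass, with Chac1 (1.53-fold, SE 0.08 on the log2 scale) and Herpud1 (1.44-fold, SE 0.07) the clearest. The ER stress list passed camera (adjusted p = 2.24e-05; adjusted p = 0.188 with an estimated correlation), with 11 lower and 1 higher adjusted over the list alone. Leaving out each array in turn gave 2 to 4 lower genes, fewest without Ad-null replicate 1, Ad-Zip8 replicate 1 or Ad-Zip8 replicate 4, and repeated quantile normalization gave 3.

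Hypoxia genes rose in 14 of 23 cases with none lower, and 9 did not pass. Those 9 included Slc2a1 (log2 change 0.01), Hk2 (0.05), P4ha1 (-0.05) and Vegfa (0.16). The list held regulator genes such as Epas1 beside hypoxia targets. Epas1, which encodes HIF-2 alpha, rose 3.86-fold (log2 change 1.95, SE 0.12, adjusted p = 1.14e-05), the adrenomedullin gene Adm 4.19-fold (2.07, SE 0.17), Egln3 2.58-fold (1.37, SE 0.13) and Pfkfb3 2.00-fold (1.00, SE 0.08). The list passed camera (adjusted p = 6.06e-14; adjusted p = 0.0520 with an estimated correlation), and 16 rose adjusted over the list alone. In the cholesterol and oxysterol list 4 of 20 rose and none fell. These were the oxysterol-making and oxysterol-converting enzyme genes Ch25h (3.91-fold, 1.97, SE 0.19) and Cyp7b1 (4.24-fold, 2.08, SE 0.12), the efflux transporter gene Abca1 (2.35-fold) and the nuclear receptor gene Rora (1.34-fold), while the 15 cholesterol synthesis members lay between -0.23 and 0.21 on the log2 scale and none passed. This list's camera call (adjusted p = 0.0243; adjusted p = 0.523 with an estimated correlation) did not pass with the replicate block (adjusted p = 0.070), after dim genes were left out (adjusted p = 0.0949), or without Ad-null replicate 2 (0.0538), Ad-null replicate 3 (0.0778), Ad-Zip8 replicate 1 (0.0785) or Ad-Zip8 replicate 4 (0.0685). Adjusted over the list alone 4 rose.

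Cell cycle genes rose almost as a whole list, with 27 of 30 higher, 3 not past the test and a median log2 change of 0.87. Top2a rose 2.56-fold (log2 change 1.36, SE 0.10, adjusted p = 2.90e-05), Birc5 2.43-fold (1.28, SE 0.10), Plk1 2.05-fold (1.03, SE 0.08) and Cdk1 1.98-fold (0.99, SE 0.08). Camera passed the cell cycle list (adjusted p = 5.69e-33; adjusted p = 0.0520 with an estimated correlation), and 28 rose adjusted over the list alone. Immediate early and MAPK genes rose in 14 of 24 cases with none lower, among them Ier3 (2.59-fold), Junb (2.24-fold) and Fosl2 (1.88-fold). Their list passed camera (adjusted p = 2.24e-12; adjusted p = 0.111 with an estimated correlation), and 16 rose adjusted over the list alone. Of 16 p53 targets 4 rose and 1 fell, with Plk2 (1.71-fold) higher and Perp (log2 change -0.58) lower, and camera did not pass them (adjusted p = 0.104, but 0.0416 without Ad-null replicate 1; 4 and 1 adjusted over the list alone).

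TGF-beta and BMP response genes fell in 5 of 18 cases and rose in 1. Tgfbi (1.67-fold) and Nog (1.58-fold) were lower and Ltbp2 (3.23-fold, SE 0.17 on the log2 scale) was higher. Camera did not pass this list (adjusted p = 0.0885, but 0.0439 without Ad-null replicate 4 and 0.0445 without Ad-Zip8 replicate 1). By limma's fry it passed as lower (adjusted p = 0.0271), and adjusted over the list alone 5 fell and 2 rose. With the replicate block, with repeated quantile normalization or without Ad-Zip8 replicate 3, 2 rose, and 3 fell without Ad-null replicate 1 or Ad-Zip8 replicate 4. Wnt genes fell in 3 of 21 cases and rose in 1, with equal counts adjusted over the list alone. Nkd1 (1.99-fold) and the Wnt antagonist gene Frzb (1.80-fold) fell and Wnt5a rose (1.65-fold). The Wnt list did not pass camera (adjusted p = 0.259) but passed limma's fry as lower (adjusted p = 0.017). None of 18 ribosomal protein genes passed over all genes or adjusted over the list alone, and their log2 changes lay between -0.09 and 0.10 (camera adjusted p = 0.858).

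Camera passed none of the marker lists of other cell types with all arrays, but limma's fry passed skeletal muscle as lower (adjusted p = 0.0117) and osteoclast (0.00149) and adipocyte markers (0.00417) as higher. Of 12 endothelial markers 1 fell, Erg (1.51-fold), with 2 lower adjusted over the list alone. The median log2 change was 0.05 against a mean of -0.03, with camera pointing downward (adjusted p = 0.940). Erg had an Ad-null mean of 7.82, far above Cdh5 (4.52), Tie1 (4.52) and Pecam1 (5.51), so its fall need not reflect endothelial cells. With 1 array left out, Erg passed only without Ad-null replicate 3 or 4. Skeletal muscle markers fell in 2 of 14 cases, both counts equal, with Tnni2 1.52-fold lower (camera adjusted p = 0.0881, but 0.0416 without Ad-null replicate 1). With 1 array left out 1 muscle marker fell, except without Ad-null replicate 2 or Ad-Zip8 replicate 2 (2). The single osteoclast marker of 9 that rose was Mmp9, also counted among the matrix-degrading enzymes, with 3 higher adjusted over the list alone (camera adjusted p = 0.0951). Adipocyte markers rose in 2 of 8 cases by either count, with the fatty acid carrier gene Fabp4 6.87-fold higher from a low Ad-null mean of 4.12 (log2 change 2.78, SE 0.36, adjusted p = 8.50e-04; camera adjusted p = 0.132), and with 1 array left out 1 rose, except without Ad-null replicate 2 or Ad-Zip8 replicate 4 (2). Blood cell markers rose in 1 of 9 cases by either count (camera adjusted p = 0.339) and in 0 with the replicate block, with repeated quantile normalization or without Ad-null replicate 1 or 4 or Ad-Zip8 replicate 1, 3 or 4.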

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

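In 244 groups of 4 arrays (each named gene in each treatment), 19 held an array far from the other 3, where chance at 1 in 20 would give 12.2. Of the 19, 6 lay in Ad-Zip8 replicate 1, 5 in Ad-null replicate 1, 4 in Ad-Zip8 replicate 2 and 2 each in Ad-null replicates 2 and 3. All values here are log2 expression.

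In Ad-Zip8 replicate 1, Cxcl5 was 11.91 (others 11.31 to 11.36), Ccl2 10.67 (9.72 to 9.77), Slc11a2 9.90 (9.61 to 9.64), Txnrd1 9.64 (9.39 to 9.42), Junb 8.32 (8.13 to 8.16) and Herpud1 10.44 (10.60 to 10.63). In Ad-Zip8 replicate 2, Slc39a1 was 9.96 (9.80 to 9.81), Chac1 8.69 (8.52 to 8.54), Mef2c 7.17 (7.29 to 7.31) and Dcn 12.63 (12.74 to 12.75).

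In Ad-null replicate 1, Col2a1 was 13.49 (others at 13.45), Gclc 8.06 (7.88 to 7.90), Serpina3n 10.58 (10.13 to 10.20), Fgfr3 10.71 (10.55 to 10.57) and Btg2 7.64 (7.30 to 7.35). In Ad-null replicate 2, Slpi was 6.63 (6.88 to 6.92) and Chst3 5.49 (5.21 to 5.25). In Ad-null replicate 3, Xylt1 was 11.64 (11.45 to 11.48) and Cd14 5.12 (5.47 to 5.51).

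Outside the named genes, a test of all 41345 probe sets called 207 of the 16010 without an annotated gene, 99 higher and 108 lower with Ad-Zip8. It also called 70 of the 1814 with several gene symbols, 44 higher and 26 lower.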

How the results depend on the processing

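Slc39a8, the counts of genes higher and lower, the 2-fold counts and the number of lists passed (14 to 17, against 15) stayed within 1.5 times of the reported values under each alternative run, except the count of lower genes without Ad-null replicate 1 (721) and without Ad-Zip8 replicate 1 (708), against 1136. With each other array left out that count was 776 to 923, the highest without Ad-null replicate 3. Leaving out dim genes gave 1297 higher and 1625 lower, and the variance trend 1439 and 1688. The replicate block gave 1278 higher and 1059 lower, of which 1116 and 927 were also called without it. It changed the calls of Slc39a4 (adjusted p = 0.0706), Slc39a10 (0.0699) and Camp (0.0697) and of 1 list, and no other call of the 120 called named genes or of the 29 lists as a whole. No direction of a called named gene or list reversed. Over the alternatives that keep all arrays, 12 of 835 values of named genes no longer passed and 4 newly passed. With 1 array left out 74 of 968 no longer passed, all in genes with an adjusted p between 0.0176 and 0.0443. With 1 array left out 4 list calls were lost, all of the cholesterol and oxysterol list, and 5 were gained. The lists are less secure than the genes, since none of the 29 passed camera with an estimated correlation. The median log2 change of all genes was -0.02, and -0.04 at the farthest, after dim genes were left out. Signals near 13.8 or near background limit what differences the arrays can show.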

Other observations

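The gene groups of the first 2 paragraphs were chosen after the largest changes had been seen, so their tests are not independent of them. The 3 patterns weighed after them were also picked from those changes, and the test of single heat shock genes with 1 array left out was chosen after its result was seen. Acute-phase genes rose in 12 of 19 cases (median log2 change 0.99, camera adjusted p = 1.25e-15 over the 4 added lists; adjusted p = 0.00515 with an estimated correlation), 4 of the 19 being members of the fixed lists too, and 13 rose adjusted over the list alone. Beside Hp, Lbp, Saa2 and Saa3, Ptx3, which encodes pentraxin 3, rose 2.46-fold (SE 0.11 on the log2 scale). Complement genes rose in 7 of 13 cases and fell in 1, or 8 and 1 adjusted over the list alone and 8 and 2 with the replicate block (adjusted p = 1.79e-05; adjusted p = 0.00710 with an estimated correlation). Cfb, the gene of complement factor B, rose 13.1-fold (log2 change 3.71, SE 0.17) and the C1 inhibitor gene Serping1 5.13-fold (2.36, SE 0.23), while the complement regulator gene Cd55 fell 1.83-fold (adjusted p = 0.0304) and did not pass without Ad-null replicate 1, 2 or 3 or Ad-Zip8 replicate 4.

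The sizes of change of Serping1, Cd55 and Tap2 are uncertain, as each had a group mean below the array medians. Antigen presentation genes of MHC class I rose in 5 of 16 cases, or 9 adjusted over the list alone (adjusted p = 9.27e-08; adjusted p = 0.00436 with an estimated correlation). H2-Q10 rose 8.71-fold, although probes of this gene family are hard to assign, Tapbp 1.86-fold and Tap2 1.62-fold, while B2m had a log2 change of 0.09 (SE 0.07). Fatty acid genes often placed under PPAR control rose in 5 of 13 cases with none lower, or 7 higher and 2 lower adjusted over the list alone (adjusted p = 2.66e-04; adjusted p = 0.104 with an estimated correlation). With the replicate block 7 rose and 1 fell, and the adjusted p was 0.0408 with an estimated correlation. Vnn1 rose 14.6-fold, Angptl4 5.67-fold and Plin2 1.70-fold.

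The microRNA genes between Dlk1 and Dio3, neighbours in an imprinted region, were lower as a block with Ad-Zip8. Of 43, 36 fell and none rose, and their median log2 change was -1.04, in a region picked because these genes had been seen to fall. As neighbours they may be read from shared transcripts, so the 36 need not be separate events. With whole-transcript labelling, the values do not tell mature microRNAs from longer transcripts. A general drop of small RNA probe sets is argued against by the 510 small RNA genes elsewhere, whose median was 0.0595 (bootstrap interval over genes 0.03 to 0.08). Many of the 510 were dimmer than the region's genes and had less room to fall. The 129 with a mean signal at or above the region's microRNA median had a median log2 change of 0.11. A single array is argued against by medians of the region's microRNA genes that stayed at -0.97 or beyond with each array left out. As a hypothesis, the fall may reflect lower long transcripts of the same region: Rian (log2 change -1.03, SE 0.14, adjusted p = 0.00122) and Meg3 (-0.48, SE 0.11, adjusted p = 0.0200) fell, with a median of -0.75, and so did 4 of 5 small nucleolar RNA genes there and the flanking gene Dlk1 (-0.44, SE 0.07). The long noncoding genes 3110009F21Rik (-0.03, SE 0.09, adjusted p = 0.899) and Dio3os (0.10, SE 0.08, adjusted p = 0.516) and the other flanking gene Dio3 (-0.11, SE 0.13, adjusted p = 0.682) did not pass. Their Ad-null means of 5.07, 5.58 and 4.58 lay near or below the array medians, where differences are compressed. Whether the fall covered all long transcripts there therefore cannot be told. Whether processing of the region or transcription differed cannot be read from these arrays, and no effect of zinc itself was tested.

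The rise of inflammatory mediators could in principle come from more macrophages among the Ad-Zip8 cells. The macrophage marker median of -0.0382 (bootstrap 95% interval -0.12 to 0.10) argues against it as the whole source, being far below the median of 0.86 for all 38 mediators. The mediators that rose had a median of 1.62, which is high by selection, since they were picked by their rise. Bootstrap intervals here and below resample the genes of a list, not the arrays. The markers did not move together: Cd14 (log2 change 1.39, SE 0.15) and Cd68 (0.83, SE 0.13) rose, Laptm5 fell (-0.72, SE 0.10), and C1qa (-0.04, SE 0.10), Csf1r (-0.09, SE 0.12) and Lyz2 (0.10, SE 0.12) did not pass. Most of the 15 lay near or below the array medians, where differences are compressed, so a small share of macrophages is not excluded. A single array is argued against too. With each array left out the list's median, 0.86 with all arrays, was lowest at 0.79, without Ad-null replicate 3. It was farthest from 0.86 at 0.97, without Ad-null replicate 1. A stronger antiviral response to the vector stays open. The interferon list's median was 0.18 with an upper bound of 0.29, above the bound of 0.2 set for excluding it, and no uninfected cells are among the arrays.

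For the heat shock genes, handling stress at harvest could not be excluded. The immediate early list had a median log2 change of 0.43 (bootstrap 95% interval 0.23 to 0.85), but missed the threshold in camera with an estimated correlation (adjusted p = 0.111). The treatment itself may raise these genes, so the list cannot tell handling from it. Of its 24 members 14 rose, such as Dusp6 (1.28) and Fos (0.85), while Jun (0.12), Dusp1 (0.05) and Nr4a1 (-0.06) did not pass. The heat shock list's median was only 0.08, and 0.0535 with Ad-null replicate 2 left out, which decides nothing about a single array. The 5 heat shock genes that rose argue against one, since all 5 passed with each array left out and each kept at least 0.887 of its log2 change. The 2 groups of Hspa1a and of Hspa1b values did not overlap. An effect of ZIP8 or its metals on protein folding stays an untested possibility, and Dnajb1, Hsph1 and Bag3, genes of the same stress response, had log2 changes of 0.28, 0.09 and -0.05, none past the threshold.

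Among the 35 ways to split the 8 arrays into 4 and 4, only 1, the real one, gave 2352 genes, and the highest other gave 15. For genes changed at least 2-fold it was again 1 of 35, with 327 against 14. In both cases this is under 0.05 of the splits and the lowest share possible. All other splits mix the 2 treatments, so a treatment effect widens the spread within their groups and lowers their counts. They therefore do not show how many genes would be called without an effect. Those 15 genes came from replicates 1 and 2 set against 3 and 4 across both treatments. Of the 8 splits that part all 4 same-numbered pairs, the 7 others called 0 genes, but 8 splits are too few for a share under 0.05. The number of lists passed by camera, 15, was also reached by 1 of 35 splits, but the highest other gave 14. The 16 splits with 3 arrays of 1 treatment and 1 of the other, which keep part of the real difference, passed 5 to 14 lists while calling 0 genes, and the 18 splits with 2 arrays of each passed 0 to 1.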
